A study of Mus musculus with 2 samples.

How the data were processed

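Viable CD45-positive cells, the white blood cells of the host, were sorted from subcutaneous tumours of B16-F10, a mouse melanoma cell line, on day 14 after injection. The tumours carried either a knockout of FDPS (farnesyl diphosphate synthase, an enzyme of the mevalonate pathway) or no such knockout. Per the labels, 3 tumours were used per group, and each group gave 1 droplet single-cell RNA library. The labels give no map from cells to tumours, so the tumours of a group could not be told apart. The design therefore has 2 libraries and no replicate, and neither a test between groups nor a check of spread between replicates was possible. Each comparison below is of the 2 libraries and not of the 2 conditions. Exact intervals (Clopper-Pearson for shares, Poisson for summed molecules) cover counting error only.

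The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers. They were made with Cell Ranger 7.2.0, per the file headers, and aligned to mm10, per the submitters' processing notes. The gene annotation behind them is not given in the sources used here. Gene positions were taken from GENCODE vM21 on the GRCm38 build, in which 32158 of the 32285 gene identifiers of the files (99.6%) were found. The knockout library held 9130 barcodes with 127186298 UMIs and the control library 10882 barcodes with 208936136 UMIs. Barcodes held 500 to 262038 UMIs in the knockout library and 500 to 331696 in the control library.

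Cells were kept with at least 200 detected genes and under 10% mitochondrial UMIs. This left 8697 barcodes (95.3%) of the knockout library and 9415 (86.5%) of the control library. The mitochondrial limit removed 4.67% of knockout and 13.5% of control barcodes, and 30 knockout barcodes and 0 control barcodes had too few genes. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0.0115% of knockout and 1.87% of control cells. The cells with the highest scores were therefore removed at an expected rate of 0.8% per 1000 barcodes, which was 7.30% (635 cells) and 8.71% (820 cells). This left 8062 knockout and 8595 control cells.

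Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering of both libraries together at resolution 1.0. Clusters of T, NK and innate lymphoid cells and clusters of monocytes, macrophages and dendritic cells (DCs) were clustered again at resolution 1.0. Clusters were named from 21 marker sets. A name needed at least 3 markers detected in at least 25% of cells and a margin of 0.1 over the next set. Among myeloid cells the margin was required between monocytes or macrophages and DCs, and not between monocytes and macrophages or between types of DC. Within the T, NK and innate lymphoid clusters it was required between subtypes, and the set of genes common to all T cells was not counted as a rival. Clusters with markers of 2 types at similar level, or with few UMIs per cell and no marker among their leading genes, stayed unresolved or unnamed. The top 10 genes of each cluster were then checked for markers of other classes. They were ranked by their fold over all other cells, a choice made after seeing the data. By that rank, a CD8 T cluster (T8) had 1 gene of its own marker set and 1 of the NK set, and the cluster named ILC2 (T14) 1 of its own set and 1 of the mast cell set. Mcpt4, Cma1 and Tpsb2, mast cell genes in no marker set, were also among the top 10 of T14. By its leading genes T14 is thus closer to mast cells, and the name, which the marker sets gave, is uncertain. Ranking within the lineage would have given T8 1 NK marker and 0 of its own class, and the unresolved cluster M4 1 marker of ILC2. A rule that clusters named as DCs but led by macrophage genes become unresolved phagocytes was also chosen after seeing the data. Unresolved phagocytes made up 9.18% of knockout and 0.0956% of control cells. Shares are of all retained cells outside clusters named as melanoma (8048 knockout and 8371 control cells), and no cluster was named as fibroblast, endothelial or erythroid. They include the unnamed cluster 23 (35 knockout and 620 control cells, median 723 UMIs), which had melanoma and myeloid markers at similar level and melanoma genes among its leading genes.

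UMIs were summed per class and library and scaled to CPM, which is counts relative to a common total per class and library. Differences are log2 ratios of CPM plus 5, knockout over control, so a negative value means a lower level in the knockout library. Classes with at least 100 cells in each library and genes with at least 10 CPM in the mean of the libraries were used. Before the data were examined, 18 gene lists were fixed. They were type I interferon-stimulated, interferon-gamma-induced, MHC class I presentation, MHC class II presentation, cytotoxic effector, inhibitory receptor and exhaustion, naive and memory T, regulatory T effector, immunosuppressive macrophage, inflammatory macrophage, hypoxia and glycolysis, mevalonate and sterol synthesis, proliferation, chemokine, nucleic acid sensing, dissociation and heat shock, melanoma, and erythroid genes. The last 3 served as measures of handling, of other cells and of free RNA. The median of a list with at least 4 measured members was set against 10000 random lists of the same size, matched on level in 20 bins. A median outside the central 95% of these is given as such, which describes the libraries and is no test between groups. Members count as higher or lower at 1.5-fold.

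Genes are named by a rule fixed with the lists. For the 4 classes of resolved type with the most cells, it takes the 6 genes with the highest and the 6 with the lowest log2 ratio. These are taken among genes with at least 30 CPM in the mean and 50 UMIs in the higher library. T cells of unresolved subtype (937 knockout and 142 control cells) were passed over, though they outnumbered NK cells (709 and 247). Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes and predicted genes were left out. It adds up to 4 members of each list with the largest ratio in the class described, the markers that name a class, and Fdps. A fold against a level of 0 was computed against 3 UMIs over the class, or against 3 cells for a share. Dividing cells were counted as those with at least 2 UMIs of proliferation genes after thinning to 1000 UMIs per cell. Free RNA per class was estimated from transcripts that the class should lack, which were those of macrophages in lymphocytes and of T cells in the other classes. The profile subtracted was that of the whole library, so RNA of macrophages or tumour cells beyond their part in it is not removed in myeloid classes.

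The steps were tested on simulated counts before use, with 200 genes changed 2-fold. In CD8 T, NK, monocyte and macrophage, and conventional DC classes (5246, 5322, 5164 and 5275 genes) 100.0%, 98.0%, 100.0% and 100.0% of these were recovered. Of 40 unchanged lists, 90.0%, 95.0%, 92.5% and 95.0% lay inside the central 95%. A free RNA share of 3% was estimated as 3.03%, 3.22%, 3.10% and 2.83%. The RNA added had the profile that the estimate assumes, and the estimating genes were first removed from the class. This recovery thus checks the computation and not that assumption. The simulated counts held counting error only, without differences in cluster mix, gene span or tumour RNA. Alternatives covered the cell filter, doublets, clustering resolution and genes, separate clustering of each library, a marker gate in single cells, scaling, weighting of cells, prior, level minimum and thinning. Others, added after seeing the data, covered free RNA, equal weights of clusters, gene span, totals without mitochondrial and ribosomal protein genes, and the placing of unresolved phagocytes and unnamed cells. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.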

Results

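The immune cells of FDPS-deficient melanomas were compared with those of control melanomas, a question raised by work on FDPS loss together with immune checkpoint blockade. Transcripts of single CD45-positive cells were counted in 2 libraries, 1 from FDPS-knockout tumours and 1 from control tumours, each from 3 tumours on day 14. The median barcode held 10732.5 UMIs and 3358.5 genes in the knockout library and 12252 UMIs and 3501.5 genes in the control library. After filtering, 8048 knockout and 8371 control cells lay outside the melanoma clusters. All differences below are between these 2 libraries.

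T cells were the most abundant class of the knockout library, and monocytes and macrophages that of the control library. T cells made up 51.4% (95% interval 50.3 to 52.5) of knockout cells and 26.4% (25.5 to 27.4) of control cells. Monocytes and macrophages made up 10.5% (9.86 to 11.2) and 51.2% (50.2 to 52.3), which was 4.87-fold lower (4.55 to 5.21) in the knockout library. Unresolved phagocytes (9.18% and 0.0956%) are not in this class. Counting them with it moved the knockout over control ratio from 0.205 to 0.384, outside the counting interval. Per monocyte or macrophage there were 4.88 T cells in the knockout library and 0.516 in the control library. The knockout library also held larger shares of NK cells, conventional CD4 T cells, plasmacytoid DCs, and a cluster named as group 2 innate lymphoid cells (ILC2) that also carried mast cell genes. Shares add up to a whole, so the lower share of monocytes and macrophages by itself raises those of all other classes. No alternative left monocytes and macrophages out of the total. A larger share thus need not hold among the remaining cells. Monocytes and macrophages were 847 of 8048 knockout and 4289 of 8371 control cells. Among the cells outside them, CD8 T cells (2166 knockout and 1879 control) were a smaller part of the knockout than of the control library. The same held for conventional DCs (848 and 614). All T cells (4135 and 2214) were then only a slightly larger part of the knockout library.

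Within the T cells, the knockout library held a wider mix of subsets. CD8 T cells were 26.9% (25.95 to 27.9) of knockout and 22.4% (21.6 to 23.4) of control cells, a ratio of 1.20 (1.14 to 1.27). CD4 T cells other than regulatory cells were 9.36% (8.73 to 10.0) and 0.812% (0.631 to 1.03), 11.5-fold (9.004 to 14.7) higher in the knockout library. Regulatory T cells, named by Foxp3 and Il2ra, were 3.19% and 1.37%, a ratio of 2.32 (1.87 to 2.89). CD8 T cells were thus 52.4% of knockout and 84.9% of control T cells, and CD4 T cells 18.2% and 3.07%. There were 8.43 CD8 T cells per regulatory T cell in the knockout library and 16.3 in the control library. T cells whose subtype could not be resolved made up 11.6% and 1.70% of cells, a ratio of 6.86 that ran from 2.59 to 7.5 over the alternatives. They were 22.7% of knockout and 6.41% of control T cells. Their highest subtype score was that of CD8 T cells (0.453), and no alternative counted them as such. The CD8 T shares and the number of CD8 T cells per regulatory T cell are therefore uncertain. Gamma-delta T cells were few, with 22 knockout and 10 control cells. NK cells, named by Ncr1 and Klrb1c, were 8.81% (8.20 to 9.45) and 2.95% (2.60 to 3.34), 2.99-fold higher (2.59 to 3.44) in the knockout library. The cluster named ILC2, a name left uncertain by its mast cell genes, made up 1.53% of knockout cells and 0 of 8371 control cells. Against a floor of 3 cells in the control library (0.0358%), its share was 42.65-fold higher.

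Among myeloid cells, monocytes were 6.78% of knockout and 24.9% of control cells, 3.68-fold lower in the knockout library. Macrophages, named by the complement genes C1qa, C1qb and C1qc, were 3.74% and 26.3%, 7.03-fold lower. The line between both was uncertain, since 887 control cells named monocytes lay in a cluster with scores of 0.558 for monocytes and 0.554 for macrophages. Over the alternatives the ratio ran from 0.241 to 0.465 for monocytes and from 0.108 to 0.490 for macrophages. Type 1 conventional DCs (cDC1), which carry Xcr1 and Clec9a and cross-present antigen, were 3.27% and 1.62%, a ratio of 2.01 (1.64 to 2.47). Type 2 conventional DCs (cDC2) were 5.65% and 3.74%, a ratio of 1.51 (1.31 to 1.74) that ran from 1.43 to 5.05 over the alternatives, highest with the marker gate in single cells. Mature DCs, which carry Ccr7 and Fscn1, were 1.62% and 1.97%, a ratio of 0.820 (0.653 to 1.03). The 3 DC classes together were 10.5% and 7.33%, a ratio of 1.44 (1.30 to 1.59), and mature DCs were 15.3% of them in the knockout and 26.9% in the control library. Plasmacytoid DCs were 2.01% and 0.382%, 5.27-fold higher (3.61 to 7.68) in the knockout library. B cells, at 1.69% and 1.72%, had a ratio whose interval held 1 (0.779 to 1.24). Neutrophils were 1.28% and 1.65%, a ratio of 0.776. Unresolved phagocytes, with genes of both macrophages and DCs, numbered 739 knockout and 8 control cells. Counting them with monocytes and macrophages moved that ratio from 0.205 to 0.384, and counting them with DCs moved the DC ratio from 1.44 to 2.65. Clustering each library on its own moved the ratio of monocytes and macrophages to 0.354. Cells left without a name were 3.06% of knockout and 8.18% of control cells.

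**Figure D1:**
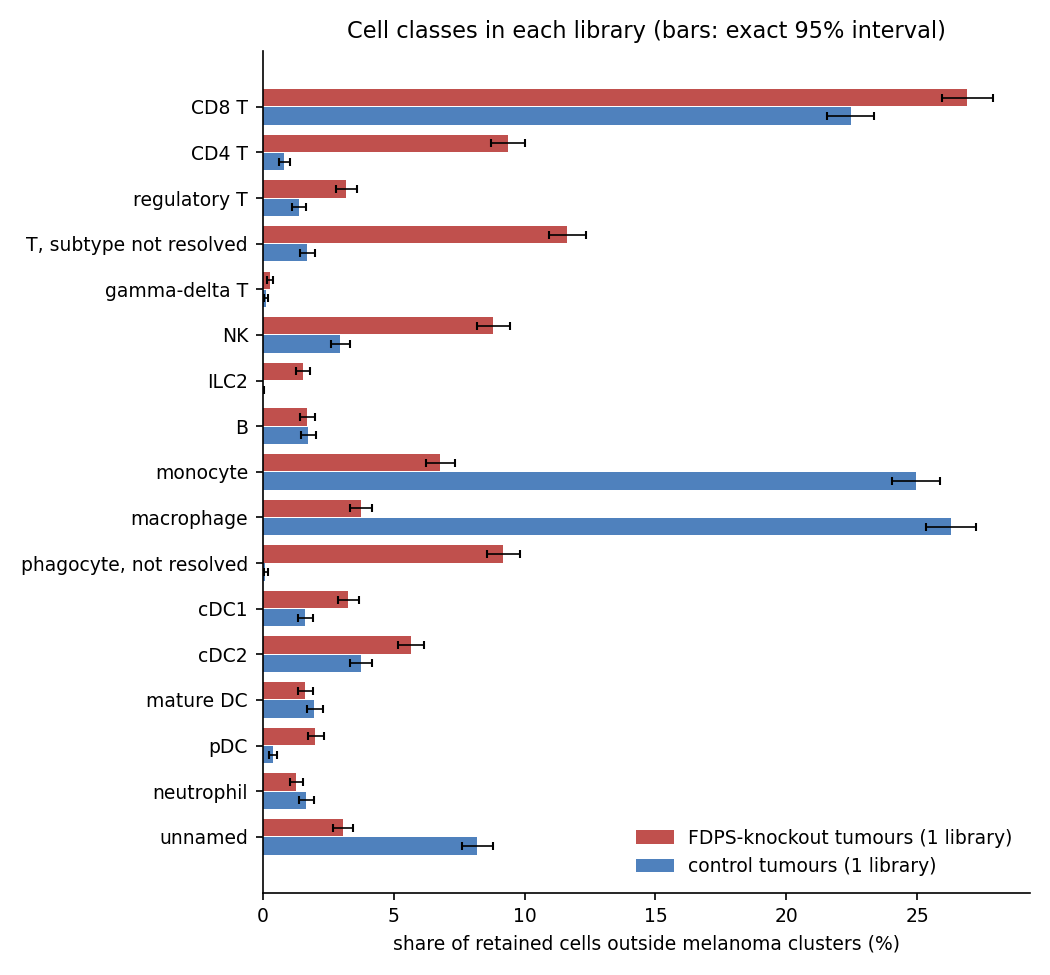
Share of each cell class among retained cells outside melanoma clusters, in percent, for the knockout and control libraries, with exact 95% intervals as error bars. Monocytes stand at 6.78% and 24.9%, macrophages at 3.74% and 26.3%, unresolved phagocytes at 9.18% and 0.0956% and CD4 T cells at 9.36% and 0.812%.

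CD8 T cells of the knockout library had more transcripts of naive and memory genes and fewer of granzymes and glycolytic enzymes. Tcf7, a transcription factor of memory-like T cells, was at 65.9 CPM (63.3 to 68.5) in the knockout and 4.47 CPM (3.90 to 5.10) in the control library, 14.7-fold higher in the knockout library. Gzmc, a granzyme of strongly stimulated killer cells, was at 1.66 CPM (1.27 to 2.12) and 470 CPM (464 to 476), 284-fold lower in the knockout library. Most knockout CD8 T cells lay in clusters T1, T2, T7 and T3 and most control CD8 T cells in clusters T8, T12, T2 and T15. These values are therefore of different CD8 T cell states as well as of different libraries.

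All 8 measured genes of the naive and memory list were higher in knockout CD8 T cells, with a median log2 ratio of 1.87, above all 10000 random lists. Besides Tcf7 (log2 ratio 2.90), they included Bach2, a repressor of effector differentiation (250 and 41.7 CPM, 2.45), Slamf6 (56.9 and 9.10 CPM, 2.13) and S1pr1, the receptor for exit from tissue (26.1 and 2.47 CPM, 2.06). With the clusters weighted equally the list median was 0.225, inside the central 95% of random lists. Outside the lists, Aff3 (142 and 12 CPM, 3.11), Fgf13 (171 and 25.9 CPM, 2.51) and Cxcr3, the receptor for Cxcl9 and Cxcl10 (65.0 and 7.92 CPM, 2.44), were also higher in the knockout library. With clusters weighted equally the log2 ratios of Tcf7, Bach2, Aff3, Fgf13 and Cxcr3 were 0.66, 0.32, 0.36, 0.35 and 0.97. Retnla was at 66.9 CPM (64.4 to 69.6) in knockout and 0.0204 CPM (0.000517 to 0.114) in control CD8 T cells. It was at 2579 CPM in knockout macrophages and was also a leading gene of the unresolved phagocytes (739 knockout and 8 control cells). Free RNA with the profile of the whole library, estimated from macrophage genes, was 2.81% of knockout and 2.28% of control CD8 T cell UMIs. The log2 ratio of Retnla in CD8 T cells was 3.84 and ran from 1.14 to 6.06 over the alternatives. The lowest value was that with this free RNA subtracted, so RNA of other cells is not excluded as the main source of Retnla there.

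The cytotoxic effector list had a median of -0.90 in CD8 T cells, below all random lists, with 2 of its 15 measured members higher, 8 lower and 5 within 1.5-fold. The lowest were granzymes. Gzmc had a log2 ratio of -6.16 (gene ENSMUSG00000079186, chromosome 14, 56231441 to 56234656 on GRCm38). Gzmf was at 0.368 and 146 CPM (-4.82). Gzme and Gzmd had 0 UMIs in knockout CD8 T cells against 74.1 and 71.8 CPM in control cells, at least 941-fold and 911-fold lower. Gzmc, Gzmd, Gzme and Gzmf are near-identical neighbours on chromosome 14, so the split of UMIs between them is uncertain. The chemokine gene Ccl5, also on this list, was at 4078 and 1717 CPM (1.25). Myo10 (-3.58) and AA467197 (-3.27) were the other 2 of the 6 lowest named genes. With clusters weighted equally Gzmc, Myo10 and AA467197 were at -5.24, -2.56 and -2.28.

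The inhibitory receptor and exhaustion list had a median of -0.03 in CD8 T cells, inside the central 95% of random lists. Of its 12 measured genes, 2 were higher, 2 lower and 8 within 1.5-fold. Tox, a transcription factor of exhausted T cells, was at 2610 and 1191 CPM (1.13) and Tigit at 61.3 and 32.7 CPM (0.81). The activation receptor gene Tnfrsf9 was at 165 and 520 CPM (-1.63) and Ctla4 at 109 and 288 CPM (-1.37). The regulatory T effector list, whose genes activated CD8 T cells also carry, had a median of -1.33 in CD8 T cells, with 1 of 8 members higher and 6 lower, and ran from -1.49 to -0.64 over the alternatives. Tnfrsf4 was its lowest member there (35.5 and 193 CPM, -2.29).

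Genes of hypoxia and glycolysis were lower in CD8 T cells of the knockout library, with a median of -1.27, below all random lists, and 13 of 15 members lower. Bnip3 was at 8.72 and 46.5 CPM (-1.91), Aldoa at 361 and 1121 CPM (-1.62) and Tpi1 at 228 and 688 CPM (-1.57). With clusters weighted equally the list median was -0.67. The type I interferon-stimulated list had a median of 0.07 (18 of 21 genes within 1.5-fold), inside the central 95%, and -0.21 with clusters weighted equally. Its member Isg15 was at 35.8 and 96.4 CPM (-1.31). The interferon-gamma-induced list (0.05, 14 of 15 within 1.5-fold), MHC class I presentation (-0.18, 13 of 15) and nucleic acid sensing (0.11, 10 of 12) also lay inside the central 95% in CD8 T cells. With sums scaled by the median ratio of genes, the interferon-stimulated, interferon-gamma-induced and nucleic acid sensing medians in CD8 T cells were below 0 (-0.06, -0.11 and -0.04). The median of all measured genes was at 0.17 in CD8 T cells, 0.13 in conventional DCs, 0.11 in NK cells and 0.08 in monocytes and macrophages, a shift that the random lists share. The mevalonate and sterol synthesis list had a median of -0.34, below the central 95%, with 17 of 19 members within 1.5-fold and Fdps lowest (-1.30). Ribosomal protein genes took 17.2% of knockout and 23.5% of control CD8 T cell UMIs. The log2 ratio also went with gene span. In CD8 T cells its median was -0.25 in the shortest 25% of genes and 0.54 in the longest 25%. These signs held in each of the 10 classes examined, with -0.454 and 0.625 in macrophages. Apart from Fdps, single genes, above and below, were not matched on span. Of the named genes, Aff3, Fgf13, Agmo, Dpp10 and Dscam are long and higher, and Gzmc, Fabp5, Ccl7 and Spp1 short and lower. Cxcr3, Retnla and Cd209f (short, higher) and Pde4d and Syn3 (long, lower) go the other way. Span is thus not separated from the ratios of genes that follow the trend.

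Regulatory T cells of the knockout library had more Klf2 (55.9 and 5.70 CPM, 2.51), Bach2 (130 and 18.6 CPM, 2.51) and S1pr1 (72.2 and 13.5 CPM, 2.06), and 7 of the 8 measured naive and memory genes were higher (median 0.99). The regulatory T effector list, at 0.24, lay inside the central 95%, with 4 of 12 members higher, 2 lower and 6 within 1.5-fold. Il10, an immunosuppressive cytokine gene, was at 168 and 44.5 CPM (1.80) and Icos at 727 and 337 CPM (1.10). Hypoxia and glycolysis genes were lower in regulatory T cells (median -0.88, 10 of 16), as were mevalonate and sterol synthesis genes (-0.55, 9 of 19). Regulatory T cells lay in clusters T5 (230 knockout and 77 control cells) and T16 (27 and 38), the latter with genes of cell division, so the mix of clusters also differed. Hmgcs1, an early enzyme of the mevalonate pathway, was at 19.9 and 75.1 CPM in regulatory T cells (-1.68).

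NK cells of the knockout library had fewer transcripts of cytotoxic and interferon-stimulated genes. Gzmb was at 278 CPM (267 to 290) and 1701 CPM (1645 to 1759), 6.12-fold lower in the knockout library, and Gzmc at 85.6 and 536 CPM (-2.58). Perforin (Prf1, 432 and 838 CPM, -0.95) and Gzma (2784 and 5367 CPM, -0.95) were also lower. Of 12 cytotoxic genes 8 were lower and 0 higher (median -0.64), and of 25 type I interferon-stimulated genes 13 were lower and 0 higher (-0.63). Among the latter, Rsad2 was at 5.67 and 33.4 CPM (-1.85). The hypoxia and glycolysis list was at -1.17 (14 of 15 lower) and dissociation and heat shock at -0.83 (10 of 13 lower, with Jun at 28.5 and 122 CPM). Higher in knockout NK cells were Taco1 (163 and 35.8 CPM, 2.04), Angpt1 (225 and 62.8 CPM, 1.76), Itga1 (113 and 29.9 CPM, 1.76), Igf1r (51.9 and 12.3 CPM, 1.72) and the activating receptor gene Cd226 (428 and 139 CPM, 1.58). NK cells lay in clusters T0 (569 knockout and 235 control cells) and T13 (140 and 12), so the sums also carry a different mix of clusters. In T0 alone, the log2 ratios of Itga1, Igf1r and Cd226 were 1.37, 1.12 and 1.17, and the cytotoxic and interferon-stimulated medians stayed below all random lists.

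Several of the most different NK genes are genes of other cells. Retnla (67.9 and 0.982 CPM, 3.61) went to -0.24 after the estimated free RNA was subtracted, and C1qb (5.42 and 61.8 CPM, -2.68) to 0.00. C1qb is among the macrophage genes that set the subtracted share, so its move to 0.00 was built in. Dct, a pigment gene of melanoma cells, was at 4.16 and 107 CPM (-3.61), and Ccl8 (-3.02) and Fabp5 (-3.12) were highest in macrophages and monocytes. All 9 measured chemokine genes were lower in knockout NK cells (median -1.66), led by the macrophage chemokines Ccl8 and Ccl2. Free RNA was estimated at 3.12% of knockout and 4.87% of control NK cell UMIs.

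Monocytes and macrophages of the knockout library had more transcripts of Retnla, Cd163 and MHC class II genes. Those of the control library had more of Spp1, Mmp12 and Fabp5 and of glycolysis and cell division genes. Retnla, a gene of alternatively activated macrophages, was at 970 CPM (950 to 989) and 2.19 CPM (1.88 to 2.54), 443-fold higher in the knockout library. Spp1, the gene of osteopontin, was at 14.4 CPM (12.2 to 17.0) and 531 CPM (526 to 536), 36.8-fold lower. Most knockout cells of this class lay in clusters M1, M6, M12 and M8 and most control cells in M16, M12, M17, M15, M18, M19 and M13.

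Also higher in knockout monocytes and macrophages were Cd209f (65.8 and 0.375 CPM, 3.72), the haemoglobin scavenger receptor gene Cd163 (125 and 7.001 CPM, 3.44), Abca9 (159 and 14.5 CPM, 3.08), Hpgd, which degrades prostaglandins (72.9 and 4.48 CPM, 3.04), and Agmo (93.8 and 7.78 CPM, 2.95). Lower were the elastase gene Mmp12 (10.2 and 207.5 CPM, -3.80), the fatty acid binding protein gene Fabp5 (113 and 1473 CPM, -3.65), Gpnmb (15.7 and 221 CPM, -3.45), the monocyte chemokine gene Ccl7 (108 and 882 CPM, -2.98) and Pclaf, a gene of DNA replication (8.15 and 87.9 CPM, -2.82). With clusters weighted equally, all of these and Spp1 were closer to 0. The log2 ratios of Cd209f, Cd163, Agmo, Abca9 and Hpgd were then 3.08, 2.26, 2.20, 1.53 and 1.45, and those of Spp1, Fabp5, Gpnmb, Mmp12, Pclaf and Ccl7 were -3.495, -2.35, -2.18, -1.85, -1.61 and -0.90. The immunosuppressive macrophage list went both ways. Its median was -0.09, inside the central 95%, with 4 of 16 members higher, 7 lower and 5 within 1.5-fold. It was at -1.32 in monocytes alone, below all random lists (-1.73 to -0.56 over the alternatives). In macrophages alone it was at -0.27, with 7 higher and 8 lower, and turned to 0.96 with a minimum of 50 CPM. In the latter, Arg1 was at 8.72 and 597 CPM (-5.46) and Cd163 at 353 and 10.2 CPM (4.56). For monocytes alone and macrophages alone, here and below, the alternatives did not include equal weights of clusters. Their values also contrast different clusters, such as M1 (337 knockout and 22 control cells) and M16 (27 and 887) among monocytes.

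The MHC class II presentation list had a median of 0.99 in monocytes and macrophages, above 99.2% of random lists, with 4 of 7 members higher and 0 lower. H2-Eb1 was at 3540 and 1290 CPM (1.45), H2-Aa at 3946 and 1527 CPM (1.37) and Cd74 at 6978 and 3508 CPM (0.99). Ciita, the activator of these genes, was at 410 and 71.2 CPM (2.45), while Nos2, another interferon-gamma-induced gene, was at 49.1 and 209 CPM (-1.99). The interferon-gamma-induced list as a whole was at -0.01, with 13 of 19 members within 1.5-fold. MHC class I presentation (-0.21, 12 of 15 within 1.5-fold) and nucleic acid sensing (0.11, 12 of 14) were inside the central 95% as well. The inflammatory macrophage list was at 0.41, inside the central 95%, with Il1b at 604 and 191 CPM (1.63) and Ptgs2 at 249 and 93.7 CPM (1.36). Both genes led cluster M1 (337 knockout and 22 control cells) within its lineage, together with Fos and Hspa1b of the dissociation and heat shock list. Handling is thus not separated from their higher levels. The inflammatory macrophage list was at -0.47 in macrophages alone, with 5 of 10 members lower, and at 0.235 in monocytes alone, both inside the central 95%.

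All 16 proliferation genes were lower in knockout monocytes and macrophages (median -1.79), with Stmn1 at 25.3 and 152 CPM (-2.37) and Top2a at 26.9 and 143 CPM (-2.21). Hypoxia and glycolysis genes were at -1.25 (13 of 17 lower), among them Gapdh (686 and 2769 CPM, -2.004) and Ldha (254 and 915 CPM, -1.83). That median was -0.40 with clusters weighted equally, still below the central 95%. The chemokine list was at -0.55, inside the central 95%, with 7 of 15 members lower and 1 higher, and Ccl2 at 237 and 1439 CPM (-2.58). Taken apart, monocytes (-1.06) and macrophages (-1.03) both had chemokine medians below the central 95%. Type I interferon-stimulated genes were at -0.27, inside the central 95%, with 10 of 28 lower and 1 higher. This list too was below the central 95% in monocytes (-0.53) and in macrophages (-0.46), though with lists matched on gene span the latter was inside it for both lists. Isg15 was at 388 and 1028 CPM (-1.39) and Ifit1 at 81.8 and 217 CPM (-1.36). Mevalonate and sterol synthesis genes were at -0.03, with 12 of 16 within 1.5-fold, but at -0.33 in monocytes alone, below the central 95%. Genes of dissociation and heat shock were higher in the same knockout cells (median 1.38, 13 of 15), with Hspa1b at 1037 and 194 CPM (2.39) and Fos at 940 and 211 CPM (2.13). Ribosomal protein genes took 7.90% and 11.6% of UMIs.

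**Figure D2:**
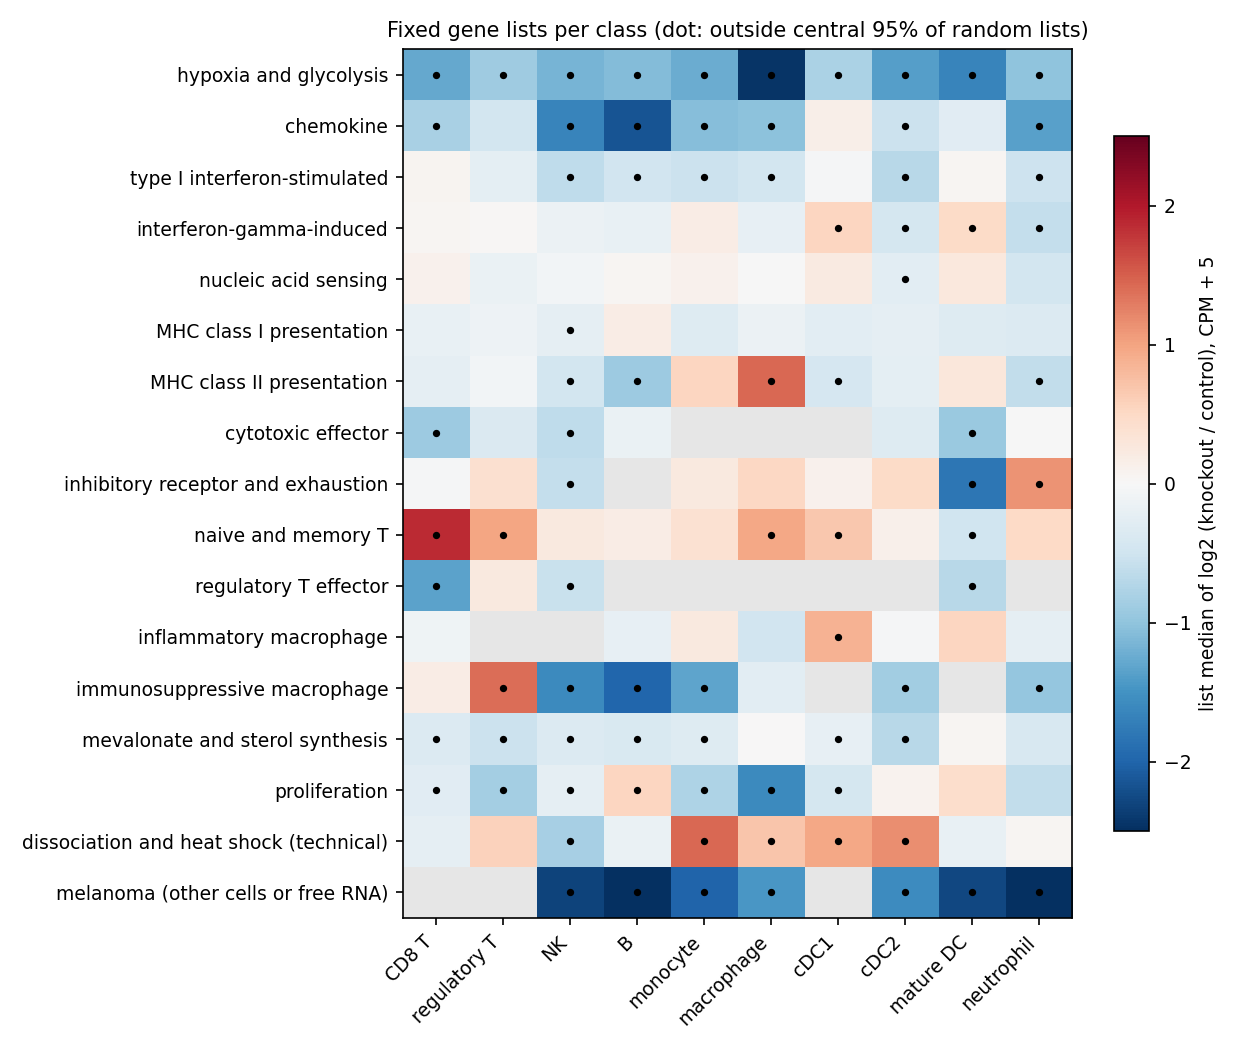
Median log2 ratio of CPM plus 5, knockout over control, of the gene lists (vertical axis) in 10 cell classes (horizontal axis), with colour for the median, dots for medians outside the central 95% of random lists and grey for lists with under 4 measured members. The hypoxia and glycolysis list runs from -2.45 in macrophages to -0.80 in cDC1 and has a dot in all 10 classes.

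Conventional DCs of the knockout library had fewer glycolysis transcripts and, in cDC2, fewer interferon-stimulated transcripts. Ifitm1, an interferon-induced membrane protein gene highest in cDC2, was at 130 CPM (124 to 135) and 1360 CPM (1338 to 1382), 10.5-fold lower in the knockout library, and the receptor-modifying protein gene Ramp3 was 21.6-fold lower (4.65 and 101 CPM). Ramp3, Syn3 and AA467197 were highest in mature DCs, so their values also carry the lower share of mature DCs among knockout DCs. With clusters weighted equally they were at -3.00, -2.37 and -2.05. Of 28 type I interferon-stimulated genes 11 were lower and 0 higher (median -0.46, below all random lists), with Isg15 at 165 and 580 CPM (-1.78) and Ifit1 at 27.1 and 84.5 CPM (-1.48). The hypoxia and glycolysis list was at -1.17 (12 of 15 lower), with Tpi1 at 107 and 360 CPM (-1.71).

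Also lower in knockout DCs were Syn3 (-2.71), Pde4d (-2.62), AA467197 (-2.44) and Fabp5 (-2.38). Higher were Dpp10 (55.2 and 5.89 CPM, 2.47), St8sia6 (71.5 and 9.48 CPM, 2.40), Dscam (106 and 18.4 CPM, 2.25), the heat shock protein gene Hsph1 (150 and 32.0 CPM, 2.07), Cd226 (193 and 44.1 CPM, 2.01) and Arhgef18 (103 and 22.4 CPM, 1.98). The dissociation and heat shock list was at 1.05 (10 of 15 higher), with Hspa1b at 527 and 134 CPM (1.94). Chemokine genes were at -0.62 (8 of 13 lower) over the mixed classes, but at 0.14 in cDC1 (5 higher, 4 lower), -0.53 in cDC2 and -0.29 in mature DCs, below the central 95% only in cDC2. The lowest of these genes in cDC2 included Ccl2 (-2.58), Ccl7 (-2.49) and Ccl8 (-2.28), and the immunosuppressive macrophage (-0.87) and melanoma (-1.58) lists were lower there too, so RNA of other cells is not excluded. Mevalonate and sterol synthesis genes were at -0.39 (17 of 20 within 1.5-fold), below the central 95%. Taken apart, they were at -0.69 in cDC2 (13 of 20 lower), -0.21 in cDC1 (3 of 19 lower) and 0.04 in mature DCs, the last inside the central 95%. MHC class II presentation genes were at -0.20 and all 10 were within 1.5-fold, while in cDC1 alone they were at -0.42, below the central 95%. Interferon-gamma-induced genes were at -0.08, inside the central 95%, with cDC1 (0.53) above it and cDC2 (-0.44) below it. Cxcl9, which draws Cxcr3-bearing T cells, was at 655 and 366 CPM (0.83).

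Of the 3 DC classes, the interferon-stimulated list was lowest in cDC2, where 16 of 28 genes were lower (median -0.69), with Oasl1 at 14.6 and 91.3 CPM (-2.30). In cDC1 the same list was at -0.02, and 13 of 20 genes were within 1.5-fold. In mature DCs it was at 0.04, with 6 of 26 genes higher and 4 lower, but at -0.63 with doublets kept, so the order of cDC2 and mature DCs is uncertain. The difference between the DC classes was not tested.

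**Figure D3:**
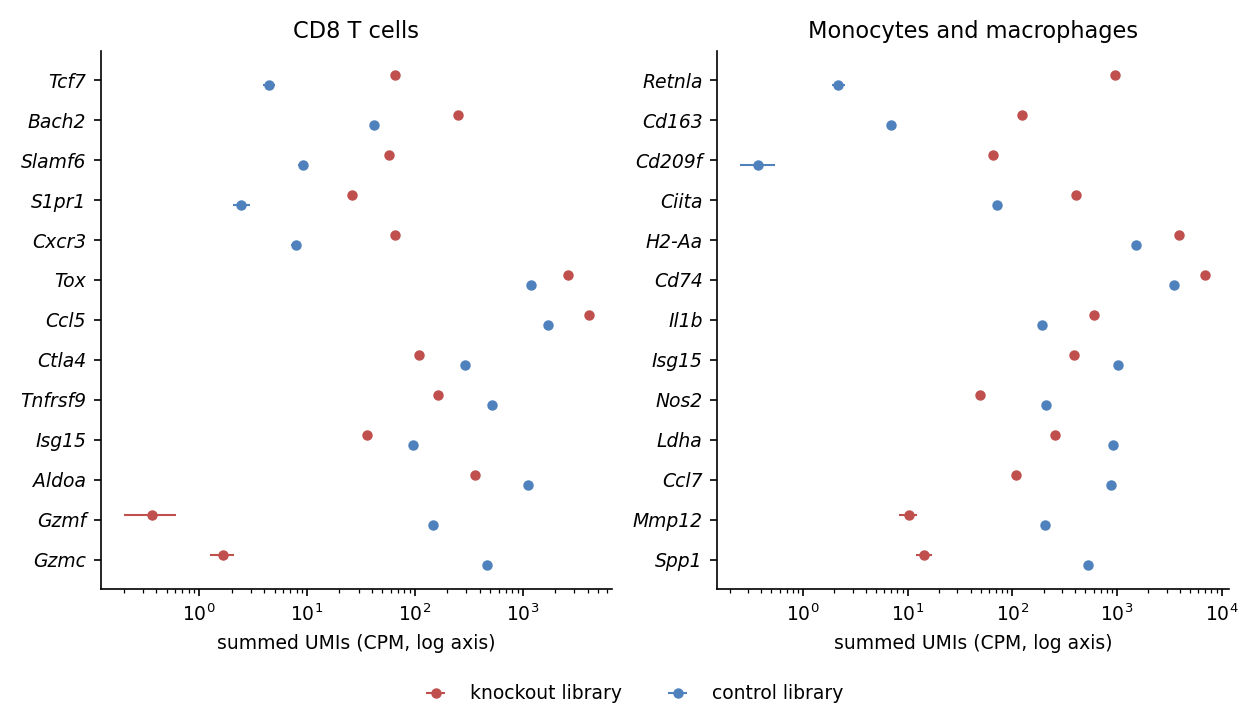
CPM on a log axis of genes named in the text in CD8 T cells and in monocytes and macrophages, for the knockout and control libraries, with exact Poisson 95% intervals as bars. Gzmc in CD8 T cells stands at 1.66 and 470 CPM and Retnla in monocytes and macrophages at 970 and 2.19 CPM.

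Dividing cells were fewer among macrophages, regulatory T cells and CD8 T cells of the knockout library. After thinning to 1000 UMIs per cell, 38.5% (36.5 to 40.6) of knockout and 53.6% (51.3 to 55.9) of control CD8 T cells had at least 2 UMIs of proliferation genes. The shares were 14.7% (10.6 to 19.7) and 35.7% (26.9 to 45.1) in regulatory T cells and 6.69% (4.13 to 10.1) and 26.6% (24.8 to 28.5) in macrophages. In monocytes and macrophages together they were 3.11% (2.04 to 4.52) and 15.4% (14.3 to 16.5). In conventional DCs (15.4% and 13.7%) and NK cells (3.98% and 3.25%) the intervals of the ratio held 1. In NK cells thinned to 2000 UMIs the order turned, with 10.5% and 16.2% (ratio 0.645, 0.450 to 0.924). Neutrophils, which do not divide, served as background, with 0 of 99 knockout and 2 of 133 control cells at 1000 UMIs. This background was 2.15% and 10.2% at 2000 UMIs and 18.45% and 30.4% without thinning. The lower NK share at 2000 UMIs is therefore not separated from background. Neutrophil median depth was 4996 and 4275 UMIs before thinning, against 12937.5 and 21110 in CD8 T cells. Without thinning the CD8 T shares were 83.6% and 92.6%. The proliferation list itself was at -0.28 in CD8 T cells, with 13 of 16 genes within 1.5-fold, and at 0.14 with clusters weighted equally.

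Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959 on the minus strand of GRCm38) was lower in the knockout library both in melanoma cells that had passed the sort and in immune cells. It was at 89.0 CPM (76.0 to 104) in 14 knockout melanoma cells and 401 CPM (393 to 409) in 224 control melanoma cells, 4.50-fold lower (3.86 to 5.25). CD8 T cells had 29.1 and 79.1 CPM (2.72-fold lower, 2.54 to 2.90), cDC1 98.1 and 240.5 CPM, cDC2 64.2 and 176 CPM, and regulatory T cells 23.9 and 80.3 CPM. Monocytes and macrophages had 19.9 and 44.8 CPM (2.25-fold lower, 1.95 to 2.60), and NK cells 9.71 and 23.6 CPM. Plasmacytoid DCs had the highest immune level, at 299 and 402 CPM. Fdps had the lowest ratio of 19 measured pathway genes in CD8 T and cDC1 cells, of 20 in cDC2 and of 14 in NK cells. In regulatory T cells Hmgcs1 was lower (-1.68 against -1.56). The knockout was made in the injected cells, so the level in host cells does not check the labels, nor does a transcript end outside an edited site.

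Melanoma transcripts also differed between the libraries in cells outside the melanoma clusters. Pmel, Mlana, Dct, Tyr, Tyrp1 and Sox10 together were at 12.7 CPM (12.05 to 13.4) in the knockout and 157.5 CPM (155.5 to 159.5) in the control library. These cells include the unnamed cluster 23, with 35 knockout and 620 control cells and melanoma genes among its leading genes. After thinning to 1000 UMIs, 1.69% of knockout and 18.0% of control cells had such a UMI, and 9.40% of control CD8 T cells, which should lack these genes, had one. The wider melanoma list was lower in each immune class with at least 4 measured members, with medians of -2.32 in NK cells, -2.59 in B cells and -1.65 in monocytes and macrophages. Erythroid genes were at 5.12 CPM (4.71 to 5.56) and 6.61 CPM (6.20 to 7.03) over all cells outside the melanoma clusters.

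**Figure D4:**
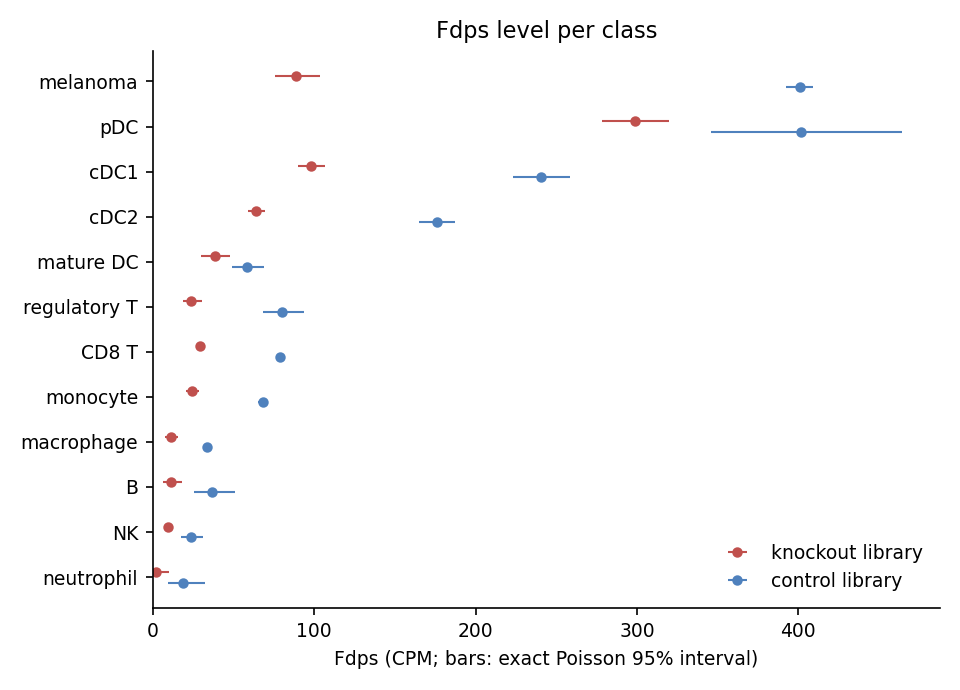
Fdps level in CPM in 12 cell classes of the knockout and control libraries, with exact Poisson 95% intervals as bars. Melanoma cells stand at 89.0 and 401 CPM and CD8 T cells at 29.1 and 79.1 CPM.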

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

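Of the tests in this part, the 4 on tumour RNA as a source of Fdps transcripts were chosen only after the result was seen, as was the grouping of classes in them. The values in this paragraph stood out because a list lay outside the central 95% of random lists in opposite directions in different cell classes, or because cells appeared that the CD45 sort should remove. The differences between classes were not tested. MHC class II presentation genes were higher in knockout macrophages (median log2 ratio 1.44, from 0.54 to 1.56 over the alternatives) and lower in knockout B cells (-0.92) and neutrophils (-0.62, from -2.49 to -0.26), inside the central 95% in some alternatives for macrophages and neutrophils. With smaller medians they were also below the central 95% in NK cells (-0.465) and cDC1 (-0.42). Genes of dissociation and heat shock were higher in knockout monocytes (1.43), cDC2 (1.17), cDC1 (0.96) and macrophages (0.70) and lower in knockout NK cells (-0.83). Melanoma clusters held 14 knockout cells (0.174% of retained cells, 95% interval 0.095 to 0.291) and 224 control cells (2.61%, 2.28 to 2.97). The unnamed cluster 23 (35 and 620 cells), which also carried melanoma genes, is not among these.

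Fdps was lower in immune cells of the knockout library, although the knockout was made in the injected tumour cells. Free RNA of tumour cells, more abundant in the control library, brings Fdps with it, and its share of the gap between libraries, computed from melanoma markers, had a median of 14.3% over 10 classes (1.48 to 63.4). It was at most 5.07% in CD8 T, regulatory T, cDC1 and cDC2 cells and at most 38.9% (95% interval over cells drawn with replacement 23.7 to 86.7) in NK, B, monocyte and macrophage cells, which argues against it as the source in the former and as the whole source in the latter. In neutrophils it was 63.4% (30.3 to 345), and in mature DCs 18.5% of a gap that was absent in 45 of 1000 draws of cells, so tumour RNA and a lower level in the cells cannot be told apart in these classes. Unequal recovery of long and short genes is argued against in 60.0% of classes, where Fdps lay below the lowest 2.5% of genes of like level and span. In CD8 T, monocyte, macrophage and mature DC cells Fdps did not lie below it (percentiles 3.4, 2.53, 7.94 and 47.9). Gene span is thus not excluded in these classes. A lower level of Fdps in host cells may remain as an untested biological explanation.

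Hypoxia and glycolysis genes were lower in all 10 classes of the knockout library. The list stayed below random lists matched on level and gene span in 100% of these classes. After the estimated free RNA was subtracted it kept 94.2% of its size (median over classes -1.21 before and -1.14 after), with the least kept in B cells (-1.08 and -0.66), and it stayed below the central 95% in each of the 10 classes. In cells without a UMI of proliferation genes it was 134% of its size in all cells (-1.26 and -1.68 over 8 classes). Those cells were chosen without thinning, which favours shallow cells and left, for example, 140 knockout and 48 control CD8 T cells. Free RNA with the profile of the whole library and gene span are each argued against as the whole cause. More dividing control cells are argued against only for the cells so chosen. With clusters weighted equally the list median went from -1.27 to -0.67 in CD8 T cells and from -1.25 to -0.40 in monocytes and macrophages together. The mix of clusters thus carried part of the difference in these classes. Equal weights were not run for monocytes alone or macrophages alone. A candidate explanation left open is a difference in the size or oxygen supply of the tumours, which the labels do not give, and with 1 library per group handling of the samples cannot be separated from the knockout.

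For the lower share of monocytes and macrophages, 2 technical explanations were looked at. With the barcodes removed by the mitochondrial limit put back and named by single-cell markers, the knockout over control ratio was 0.266, so loss to that limit is argued against. Tissue around the tumour could bring resident cells into a sort. Without ILC2, plasmacytoid DCs, B cells, unresolved T cells, unresolved phagocytes and Cd163 macrophages (2249 knockout and 398 control cells) the ratio was 0.227 (0.211 to 0.244). The sizes of these classes fixed that value, so it shows only that they alone do not account for the lower share. Surrounding tissue is not excluded, since cells of other classes that it may bring stayed in the total. An effect of tumour FDPS loss on recruitment of myeloid cells is an untested hypothesis, and a difference between individual tumours stays open as well.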

How the results depend on the processing

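Equal weights of clusters, free RNA subtraction, gene span matching, reduced totals, and the placing of unresolved phagocytes and unnamed cells were alternatives chosen after seeing the data. No paired analysis was possible because each group had 1 library. Shares stayed within their counting intervals in 140 comparisons and moved in 32. The ratios of B cells and mature DCs, whose intervals held 1, ran from 0.887 to 1.06 and from 0.597 to 1.01. List medians were the same in 2187, left the central 95% in 96, entered it in 66, and reversed in 17. Named genes were the same in 410, moved in 117 and reversed in 1. Fdps levels were the same in 25 and moved in 4, shares of dividing cells in 12 and 4, and the melanoma marker ratio was the same in 1. Over the alternatives, the share ratio ran from 0.195 to 0.384 for monocytes and macrophages and from 2.83 to 3.17 for NK cells, and the hypoxia and glycolysis median from -1.43 to -0.67 in CD8 T. The cause was not tested for any value below. With cells clustered per library, no control cluster was named CD4 T, plasmacytoid DC or gamma-delta T, so those ratios have no value. Whether depth limits the naming of rare classes was not tested.

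Without thinning, the ratio of dividing cells was 0.902 in CD8 T and 0.640 in monocytes and macrophages. With clusters weighted equally, log2 values were -0.88 for Fdps in CD8 T, -0.33 for chemokine in monocytes and macrophages, and in CD8 T 0.23 for naive and memory, 0.14 for proliferation and -0.21 for type I interferon genes. The list median, inhibitory receptor and exhaustion, CD8 T, was -0.083. Without unnamed cells the share ratio was 1.14 for CD8 T and 1.84 for all T. With doublets kept, proliferation was -0.52 in B and 0.004 in NK, and the conventional DC ratio 1.60. Clustered per library, ratios were 1.35 for CD8 T, 1.65 for conventional DCs and 0.354 for monocytes and macrophages. With free RNA subtracted, Retnla in NK was -0.24, chemokine in CD8 T 0.21 and interferon genes in B 0.076. With the marker gate, ratios were 1.34 for CD8 T, 1.77 for all T, 1.99 for conventional DCs and 0.267 for monocytes and macrophages. With cells weighted equally, monocytes and macrophages had -0.69 for chemokine, -0.69 for immunosuppressive and -0.48 for interferon genes and regulatory T -0.27 for immunosuppressive. The list median, proliferation, B, was -0.091. Median-ratio scaling gave -1.46 for Fdps in CD8 T. With a minimum of 50 CPM, values were 0.19 for immunosuppressive in neutrophils, 0.25 for inhibitory receptor in NK and 0.080 for interferon genes in B. With no minimum, they were -0.49 for chemokine in monocytes and macrophages, -0.27 for immunosuppressive in regulatory T, 0.26 and -0.28 for inhibitory receptor in mature DCs and neutrophils, 0.11 for naive and memory in conventional DCs, and 0.005 and 0.027 for regulatory T effector in conventional and mature DCs. With lists matched on span, inflammatory in monocytes and macrophages (0.41) reached percentile 99.0 and proliferation in CD8 T (-0.28) percentile 33.6. With response genes left out, proliferation in NK was 0.28 and the conventional DC ratio 1.67. The stricter filter gave -0.59 for chemokine and -0.33 for interferon genes in monocytes and macrophages. Counting unresolved phagocytes with DCs gave 2.65, and with monocytes and macrophages 0.384.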

Other observations

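The classes described here were chosen after their values were seen, and the fixed lists and settings apply. Type 1 DCs of the knockout library had more transcripts of interferon-gamma-induced and inflammatory genes. In cDC1, 9 of 19 interferon-gamma-induced genes were higher in the knockout library and 0 lower, with a median of 0.53, above all random lists. Cxcl9 was at 631 and 248 CPM (1.33), the guanylate-binding protein gene Gbp5 at 89.7 and 40.8 CPM (1.05) and Gbp4 at 24.1 and 8.74 CPM (1.08). The inflammatory list was at 0.87 (0.23 with no minimum level, inside the central 95%), with 5 of 8 genes higher and 1 lower. Cd40, the receptor for T cell help, was at 120 and 30.8 CPM (1.81), Tnf at 68.2 and 26.2 CPM (1.23) and Il1b at 19.0 and 71.5 CPM (-1.67). Genes of dissociation and heat shock were also higher in cDC1 (0.96, 10 of 14, above all random lists), so handling is not separated from these differences. In mature DCs the interferon-gamma-induced list was at 0.48, above 98.0% of random lists but inside the central 95% with doublets kept, with Cxcl9 at 1269 and 191 CPM (2.70) and Cxcl10 at 211 and 52.7 CPM (1.91). Tnf was at 212 and 15.4 CPM (3.41) there and Il1b at 48.1 and 378 CPM (-2.85). In cDC2 the same list was at -0.44, below all random lists, with the checkpoint ligand gene Cd274 at 139 and 360.5 CPM (-1.34) and Socs1 at 27.8 and 78.6 CPM (-1.35).

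In neutrophils of the knockout library, 11 of 19 interferon-gamma-induced genes were lower (median -0.60) and so were 16 of 17 hypoxia and glycolysis genes (-1.01) and 11 of 15 chemokine genes (-1.36). Free RNA was estimated at 8.65% of knockout and 8.44% of control neutrophil UMIs, from T cell genes. The melanoma (-2.73) and immunosuppressive macrophage (-0.96) lists were lower in these cells too, so RNA of other cells is not excluded as a source. In B cells, 7 of 10 MHC class II presentation genes were lower, with H2-Aa at 1679 and 3643 CPM (-1.11) and H2-Oa at 94.96 and 220 CPM (-1.17). B cells of the knockout library had more Mki67 (161 and 14.6 CPM, 3.08), a gene of dividing cells, and a proliferation list median of 0.54, which was -0.52 with doublets kept. After thinning, 3 of 134 knockout and 5 of 144 control B cells were dividing. The cluster named ILC2 also carried the mast cell genes Mcpt4 and Cma1 among its leading genes, and its name is uncertain. These genes were chosen after their values were seen.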
